A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

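Total RNA of Saccharomyces cerevisiae was extracted with silica matrices, amplified with Agilent's low input linear amplification kit and labelled with the Micromax kit at a service company, per the labels' protocols. Each of 6 arrays compared a tra1 mutant strain (tra1-P3408A, tra1_SRR3413 or tra1-S3463A, 2 arrays each) with the reference strain carrying TRA1, in swapped dyes. Some labels conflict. The source of array 1 of tra1-S3463A names the tra1_SRR3413 strain, and the source of 1 channel on array 2 of tra1_SRR3413 and on array 2 of tra1-S3463A names another dye than its label field. Titles and label fields were followed. Sample descriptions that name only tra1-P3408A were not used.

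Spot intensity values were made by the authors' scanner software, Agilent Feature Extraction 7.5.1, per the file headers: the mean pixel intensity and the median local background intensity of each spot are not corrected, and the processed intensity is background-subtracted (method code 7) and dye-normalized by lowess (smooth factor 0.25). The deposited log ratio is the log10 of processed red (Cy5) over green (Cy3) signals, per the file headers. Spot flags, such as well above background (2.6 background SD), saturated and outlier, are deposited as 0 or 1. The deposited series table holds log10 ratios of mutant over reference. Its scale and direction were settled from the values, since 100% of comparable gene spots equalled the turned log10 ratio of dye-normalized signals within 1e-04 on every array. Its column medians were between 0.00274 and 0.0101, so it was not centred further.

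Mean and background signals of 10807 spots per array were read into limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), background-corrected by normexp with an offset of 50 and normalized within each array by loess with control spots at weight 0. Then the 544 control spots and spots marked as non-uniform or population outliers were left out, which took 0.370% to 8.02% of the 10263 gene spots per array. Ratios were turned to mutant over reference, and spots of a gene were averaged. Each of the 6256 genes had 1 probe, in 2 spots for 4007 genes. A gene was kept if well above background in at least 1 channel on at least 2 arrays, which removed 2 genes. A further 135 genes lacked a value on some array and were not tested, which left 6119. Of the systematic names in the files, 5756 (92.0%) were in the table of the R64 assembly, whose symbols were used, and the files' names were kept otherwise. Saturated spots, 0.887% to 1.55% per array, were kept. Precision is limited by the number of arrays.

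Each allele's mean ratio was tested against 0, two-sided, with lmFit and eBayes in 1 fit of all 6 arrays (3 residual and 3.08 prior degrees of freedom), with Benjamini-Hochberg adjustment within the comparison and an adjusted p threshold of 0.05. Differences between alleles were contrasts of the same fit. The test leaves out the spread of the reference where 1 extract served several arrays. The 3 slides, named by the file headers, held 2 arrays each of different alleles: array 1 of tra1-P3408A and of tra1_SRR3413 on slide 1, array 2 of tra1-P3408A and array 1 of tra1-S3463A on slide 2, and array 2 of tra1_SRR3413 and of tra1-S3463A on slide 3. The array number marks the dye orientation per the labels, and deviations from the allele means correlated at 0.512, 0.467 and 0.930 between the alleles. The main fit, behind all values printed without a block, ignored this pairing. Fits with the array number as a block (2 residual degrees of freedom) and with the slide as a block (1 residual degree of freedom) are given as alternatives. A block takes deviations that the alleles share out of the spread, also where they come from the reference. Its p-values against 0 may therefore be too small and its counts of genes too large.

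The gene lists and the rule for named genes were fixed before the data were examined. For each allele the rule takes the 12 genes with the largest rise and the 12 with the largest fall among those that passed with 1 sign on both arrays. For a difference it takes 8 in each direction, or, where fewer than 5 genes passed in both directions together, the 5 largest moderated statistics in each direction. It also takes up to 4 members per described list by unadjusted p, and TRA1, PHO5, ADH2, LEU2, URA3, MATALPHA1 and MATA1. Lists were described, and medians and members followed through the alternatives, only where camera called them in at least 1 allele. That restriction was set after a first run over all lists, in which many medians of lists not called turned sign between alternatives, and those turns are not given here. The 33 lists, 32 written by name and 1 of cytosolic ribosomal proteins by rule, were tested per allele with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 33 lists within an allele. Of these lists 1 is not reported here. The shared reference was simulated in 100 data sets of unchanged alleles, with reference and mutant extracts assumed to vary equally.

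The alternatives were Agilent's processed signals, median centring, the deposited log ratio, quantile scaling of average intensities, no filter or a stricter filter on dim probes, the array number as a block, the slide as a block, only the arrays of a comparison, leaving out each array, array 1 of tra1-S3463A counted with tra1_SRR3413, the series table, and a stricter count with 1.5-fold on both arrays. Leaving out the arrays of slide 3, the tests of lists between alleles, and the lists of purine and outermost genes were added after seeing the data. The planned list of genes within 30 kb of a chromosome end was not made, since the genome build is not given in the sources used here. The scripts were tested on simulated data with the arrays' own spread and noise independent between arrays. Of 67 genes changed 2-fold in 1 allele, 89.6% were recovered in tra1-P3408A, 91.0% in tra1_SRR3413 and 91.0% in tra1-S3463A. At a log2 change of 0.5 it was 14.9%, 19.4% and 17.9%. In the differences 2-fold changes were recovered at 35.8% to 61.2%.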

Results

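The data are mRNA levels in budding yeast, Saccharomyces cerevisiae, from 6 Agilent dual-colour expression arrays. Tra1 is a large protein shared by the SAGA and NuA4 histone acetyltransferase complexes, and carries a domain related to the PI3K family of kinases. Each strain had its chromosomal TRA1 gene disrupted and lived on a myc-tagged TRA1 gene on a centromeric LEU2 plasmid. The mutant strains carried tra1-P3408A, tra1_SRR3413 or tra1-S3463A, alleles named after residues of the PI3K domain. The reference strain carried wild-type TRA1. There were 2 arrays for each of the 3 alleles, which the series calls biological replicates, and each array compared a mutant with the reference strain. The mutant was in Cy5 on array 1 and in Cy3 on array 2. Median Cy3 signal lay between 1167 and 3617 per array and median Cy5 signal between 1908 and 2482. Between 99.3% and 99.6% of gene spots were well above background in both channels. The number of arrays limits the precision. Values below are means of log2 (mutant / reference) ± SD over the 2 arrays of an allele (n = 2). Adjusted p is from limma over 6119 genes, and "passed" refers to that adjusted p.

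The first question is whether TRA1 itself and the plasmid behaved alike in the strains. TRA1 mRNA was higher than in the reference on all 6 arrays. It rose by 1.44 ± 0.70 in tra1_SRR3413 (2.71-fold, adjusted p = 0.0260) and by 1.24 ± 0.72 in tra1-S3463A (2.36-fold, adjusted p = 0.0496). In tra1-P3408A it stood at 1.02 ± 0.26 (2.03-fold), which did not pass (adjusted p = 0.0887) without the array number as a block and passed with it (adjusted p = 0.00369). Single arrays ranged from 0.73 to 1.93. Deviations that the alleles share, also those of the reference, leave the spread in a fit with a block. The p-values with a block in this paragraph may therefore be too small. Leaving out array 1 or 2 of tra1-P3408A ended the calls of TRA1 in tra1_SRR3413 (adjusted p = 0.0645 and 0.0641) and in tra1-S3463A (0.104 and 0.103). Leaving out array 2 of tra1_SRR3413, on slide 3, took TRA1 there to 0.94 and ended its call (0.158). Leaving out array 2 of tra1-S3463A, on the same slide, took it to 0.73 (0.310), and leaving out array 1 also ended that call (0.0576). With the slide as a block the values were 1.35 in tra1-P3408A, 1.33 in tra1_SRR3413 and 1.01 in tra1-S3463A, so the larger values of tra1_SRR3413 and tra1-S3463A rested on slide 3. In tra1-S3463A the call of TRA1 was also lost with Agilent's processed signals (1.26, adjusted p = 0.0512), the deposited log ratios (1.25, 0.0514) and the series table (1.25, 0.0516). Counting array 1 with tra1_SRR3413 left 1 array there, at 1.75, and ended the call too. With the array number as a block TRA1 passed in tra1_SRR3413 (adjusted p = 0.00108) and tra1-S3463A (0.00198), as it did with the slide as a block (0.000225 and 0.000628). In tra1-P3408A TRA1 passed without any single array of the other alleles (adjusted p = 0.0326 to 0.0466) and with the slide as a block (0.000295). Of the plasmid's marker LEU2, the values were -0.17 ± 0.13, -0.40 ± 0.04 and -0.19 ± 0.07 in tra1-P3408A, tra1_SRR3413 and tra1-S3463A. LEU2 passed in tra1_SRR3413 alone (adjusted p = 0.0483), and there leaving out any single array of the 6 ended the call. Median centring (0.111), processed signals (0.0626), the deposited log ratios (0.0717), the series table (0.0715) and only the arrays of this allele (0.231) ended it too. With the array number (0.0108) or the slide (0.00461) as a block LEU2 passed there. URA3 (-0.02, -0.12 and -0.13) and the mating-type gene MATALPHA1 (0.08, 0.14 and 0.17) passed in none of the 3 alleles. MATA1 was not measured under that name.

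The comparison of tra1-P3408A with TRA1 asks which genes depend on the residue changed in this allele. The strain had 485 genes lower and 291 higher than the reference. IMD2, which makes an enzyme of GTP synthesis, fell by 13.6-fold (-3.76 ± 0.56, adjusted p = 0.00157). The purine genes ADE17 and ADE1 fell by 13.8-fold (-3.79 ± 0.31, adjusted p = 0.000874) and 6.35-fold (-2.67 ± 0.20, adjusted p = 0.000874). The largest rise was that of PCL1, a G1 cyclin, at 3.12-fold (1.64 ± 0.56, adjusted p = 0.00959).

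Of the 776 genes called in tra1-P3408A, 241 differed by 2-fold or more, and 200 of these were lower. The remaining largest falls were those of YAR075W (-4.10 ± 0.72), SPL2 (-2.81 ± 0.36), HIS4 (-2.77 ± 0.45), AAD4 (-2.74 ± 0.57), APE1 (-2.60 ± 0.64), SNZ1 (-2.51 ± 0.10), HAB1 (-2.51 ± 0.29), BDH2 (-2.45 ± 0.14) and SHM2 (-2.34 ± 0.02), with adjusted p from 0.000874 to 0.00690. YAR075W is nearly identical in sequence to part of the IMD genes and AAD4 belongs to a family of similar genes, so their probes cannot be taken as specific. SPL2 is a regulator of phosphate uptake, HIS4 an enzyme of histidine synthesis, APE1 a vacuolar aminopeptidase, SNZ1 a vitamin B6 gene and SHM2 a serine hydroxymethyltransferase. The remaining largest rises were those of SCW10 (1.61 ± 0.24), FET3 (1.59 ± 0.10), RNR1 (1.58 ± 0.04), HXT4 (1.48 ± 0.78), SVS1 (1.44 ± 0.61), PDR12 (1.42 ± 0.14), DBP2 (1.35 ± 0.34), MNN1 (1.32 ± 0.08), YHR033W (1.27 ± 0.43), MIR1 (1.21 ± 0.06) and PIC2 (1.21 ± 0.47), with adjusted p from 0.00336 to 0.0465. Among these, SCW10 encodes a cell wall protein, FET3 a ferroxidase of iron uptake, RNR1 the large subunit of ribonucleotide reductase and PDR12 an exporter of weak acids. The phosphatase gene PHO5 fell to -2.30 ± 0.10 (adjusted p = 0.00492) and the glucose-repressed alcohol dehydrogenase gene ADH2 to -1.45 ± 0.09 (adjusted p = 0.00350).

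Among the gene lists lower in tra1-P3408A, the phosphate (Pho4) regulon had 7 of 15 tested members (8 adjusted over the list alone, 13 with the array number as a block) lower, with SPL2, PHO84 (-2.32), PHO5 and PHM6 (-0.89) leading (camera adjusted p = 1.4e-06, adjusted p = 0.205 with an estimated correlation). Of Gcn4 targets in amino acid synthesis, 15 of 36 tested members (19 adjusted over the list alone, 21 with the array number as a block) fell, led by SNZ1, LYS1 (-1.88), SNO1 (-2.00) and ADE4 (-1.16) (camera adjusted p = 3.16e-07, adjusted p = 0.180 with an estimated correlation). Hsf1 chaperone genes fell in 10 of 25 tested members (11 adjusted over the list alone, 16 with the array number as a block), among them SSE1 (-1.06), HSP82 (-1.60), CPR6 (-1.14) and HSP78 (-1.06) (camera adjusted p = 1.4e-06, adjusted p = 0.354 with an estimated correlation). Yap1 oxidative stress genes fell in 10 of 22 tested members (14 adjusted over the list alone, 14 with the array number as a block), with GTT2 (-1.96), SOD2 (-0.93), OYE3 (-1.31) and GPX2 (-1.34) leading (camera adjusted p = 1.4e-06, adjusted p = 0.413 with an estimated correlation). Msn2/4 general stress genes fell in 10 of 26 tested members (11 adjusted over the list alone, 13 with the array number as a block), such as SOL4 (-1.60), PGM2 (-0.81), PNC1 (-0.77) and MSC1 (-1.57) (camera adjusted p = 0.00133, adjusted p = 0.659 with an estimated correlation). Of the proteasome, 4 of 32 tested members (8 adjusted over the list alone, 17 with the array number as a block) fell, namely RPN7 (-0.61), PRE8 (-0.47), PRE10 (-0.86) and RPT5 (-0.44) (camera adjusted p = 6.74e-06, adjusted p = 0.205 with an estimated correlation). Glucose-repressed carbon metabolism had 4 of 21 tested members (5 adjusted over the list alone, 9 with the array number as a block) lower, namely ADH2, REG2 (-1.22), POT1 (-0.72) and CAT2 (-1.12) (camera adjusted p = 0.00983, adjusted p = 0.659 with an estimated correlation). MDH2, a malate dehydrogenase gene of the same list, rose (0.73).

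Higher in tra1-P3408A were the ribosome biogenesis genes, of which 11 of 38 tested members (14 adjusted over the list alone, 25 with the array number as a block) rose, with RPA135 (1.01), DBP9 (0.82), RRP12 (0.72) and UTP4 (0.70) leading (camera adjusted p = 1.28e-09, adjusted p = 0.180 with an estimated correlation). Respiratory chain and TCA cycle genes rose in 15 of 43 tested members (23 adjusted over the list alone, 29 with the array number as a block), among them ATP7 (1.17), QCR6 (0.71), ATP5 (0.70) and ATP14 (0.65) (camera adjusted p = 5.87e-07, adjusted p = 0.352 with an estimated correlation). In this list LSC2 alone fell (-1.05). G1 cyclin and S phase genes rose in 6 of 19 tested members (13 adjusted over the list alone, 14 with the array number as a block), including RNR1, PCL1, CLN1 (1.09) and TOS4 (0.78) (camera adjusted p = 2.05e-06, adjusted p = 0.180 with an estimated correlation). Core histone genes rose in 5 of 10 tested members (7 adjusted over the list alone, 7 with the array number as a block), namely HTA2 (0.91), HTB2 (1.02), HHF1 (0.73), HHT1 (0.68) and HTA1 (0.93) (camera adjusted p = 0.000704, adjusted p = 0.502 with an estimated correlation). With median centring HTB2 (adjusted p = 0.0564), HTA2 (0.118), HTA1 (0.165), HHF1 (0.174) and HHT1 (0.201) did not pass. Cytosolic ribosomal protein genes rose in 11 of 133 tested members (11 adjusted over the list alone, 59 with the array number as a block), led by RPS27A (0.91), RPL18B (0.91), RPS14B (0.84) and RPS26B (1.02) (camera adjusted p = 1.12e-07, adjusted p = 0.659 with an estimated correlation). Histone and ribosomal protein genes have near-identical copies, so single genes of these families are uncertain. CAT2, LSC2 and HTA1 were named after their values were seen.

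The array number as a block gave 2214 genes for tra1-P3408A and the slide as a block 2679, while without array 1 or 2 of tra1-P3408A limma called 1 and 46 genes and 70 and 56 of the 75 genes named for it lost their call. The glucose-repressed list was lost without array 2 (adjusted p = 0.0982) and with the slide as a block (0.0801), and the general stress list with the slide as a block (0.0971).

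**Figure D1:**
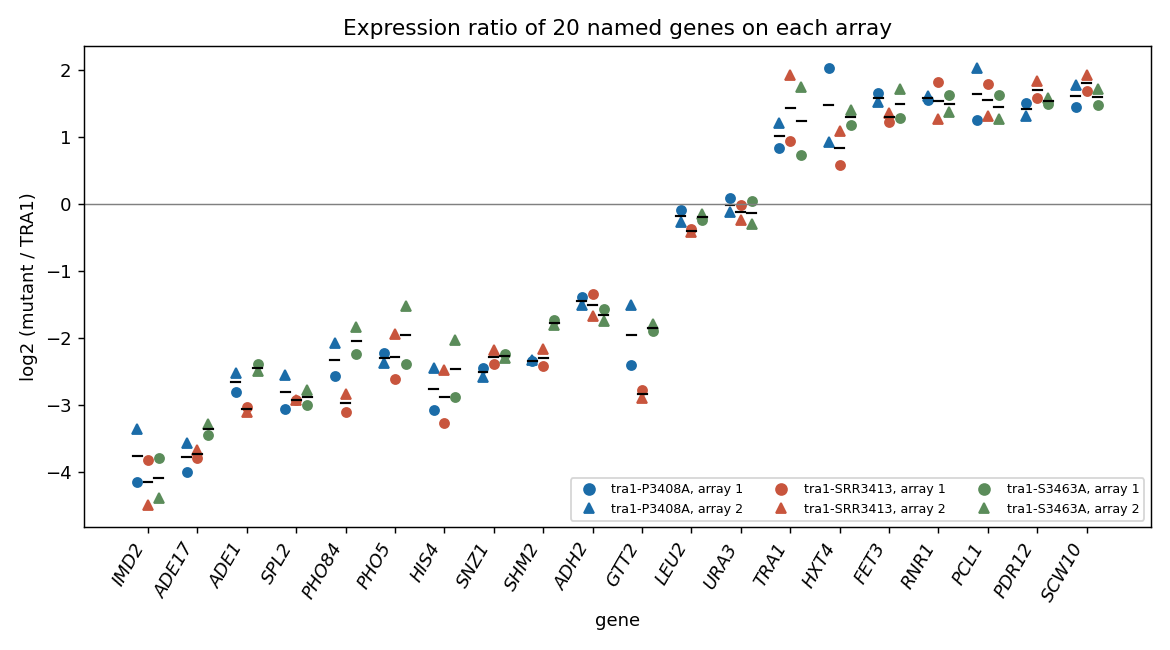
Points are log2 (mutant / reference) of each array for a selection of the named genes, with bars at the mean of the 2 arrays of an allele, n = 2. Some of the largest changes, such as those of YAR075W, AAD4 and TKL2, and the fixed gene MATALPHA1 are not drawn. IMD2 sits at -3.76, -4.16 and -4.10 in tra1-P3408A, tra1_SRR3413 and tra1-S3463A, and SCW10 at 1.61, 1.81 and 1.60.

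The comparison of tra1_SRR3413 with TRA1 asks the same of the SRR residues of the same domain. In this strain 718 genes were lower and 571 higher. The deepest falls were again in IMD2 at 17.9-fold (-4.16 ± 0.48, adjusted p = 0.000980) and ADE17 at 13.3-fold (-3.73 ± 0.09, adjusted p = 0.000519), with the near-identical YAR075W at -4.73 ± 0.46. The phosphate transporter gene PHO84 fell by 7.84-fold (-2.97 ± 0.19, adjusted p = 0.000813) and the glutathione transferase gene GTT2 by 7.17-fold (-2.84 ± 0.09, adjusted p = 0.00137). The largest rise was that of TKL2, a transketolase gene, at 4.09-fold (2.03 ± 0.95, adjusted p = 0.0375).

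Of the 1289 genes called in tra1_SRR3413, 310 differed by 2-fold or more, and 240 of these were lower. The remaining largest falls were those of AAD4 (-3.47 ± 0.20), ADE1 (-3.07 ± 0.05), SPL2 (-2.92 ± 0.000539), HIS4 (-2.88 ± 0.56), YMR090W (-2.83 ± 0.69), HAB1 (-2.83 ± 0.62) and BDH2 (-2.66 ± 0.13), with adjusted p from 0.000519 to 0.00293. The remaining largest rises were those of YBR116C (1.998 ± 0.64), YHR033W (1.87 ± 0.56), SCW10 (1.81 ± 0.17), TMA10 (1.77 ± 0.28), PIC2 (1.72 ± 0.16), PDR12 (1.71 ± 0.18), MNN1 (1.60 ± 0.09), SVS1 (1.59 ± 0.01), ATG39 (1.58 ± 0.31), PCL1 (1.55 ± 0.34) and RNR1 (1.55 ± 0.40), with adjusted p from 0.00120 to 0.0237. YBR116C overlaps TKL2, and TMA10 was saturated on 1 of its arrays. MNN1 encodes a mannosyltransferase of the Golgi and ATG39 an autophagy receptor. PHO5 fell to -2.28 ± 0.47 (adjusted p = 0.00352) and ADH2 to -1.51 ± 0.23 (adjusted p = 0.00201).

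Among the lists lower in tra1_SRR3413, the phosphate (Pho4) regulon had 9 of 15 tested members (9 adjusted over the list alone, 11 with the array number as a block) lower, led by SPL2, PHO84, PHO5 and PHM6 (-0.85) (camera adjusted p = 1.4e-05, adjusted p = 0.310 with an estimated correlation). Gcn4 targets fell in 20 of 36 tested members (21 adjusted over the list alone, 23 with the array number as a block), with SNZ1 (-2.29), LYS1 (-2.20), SNO1 (-2.03) and LYS20 (-2.58) leading (camera adjusted p = 5.29e-07, adjusted p = 0.251 with an estimated correlation). ARG8 of this list rose (0.42). Yap1 genes fell in 14 of 22 tested members (15 adjusted over the list alone, 16 with the array number as a block), such as GTT2, FLR1 (-2.12), OYE3 (-1.89) and SOD2 (-0.92) (camera adjusted p = 1.08e-06, adjusted p = 0.420 with an estimated correlation). Of the Hsf1 chaperone genes, 8 of 25 tested members (9 adjusted over the list alone, 13 with the array number as a block) fell, with SSE1 (-1.05), CPR6 (-1.02), HSP82 (-1.18) and SSA4 (-1.71) leading (camera adjusted p = 0.0146, adjusted p = 0.686 with an estimated correlation). CUR1 of this list rose (0.44). Proteasome genes fell in 8 of 32 tested members (11 adjusted over the list alone, 20 with the array number as a block), among them PRE8 (-0.74), PRE10 (-1.23), PRE1 (-0.76) and RPT5 (-0.50) (camera adjusted p = 0.000234, adjusted p = 0.310 with an estimated correlation).

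Higher in tra1_SRR3413 were G1 cyclin and S phase genes in 10 of 19 tested members (12 adjusted over the list alone, 14 with the array number as a block), with RNR1, PCL1, SWI4 (0.82) and TOS4 (0.98) leading (camera adjusted p = 1.2e-05, adjusted p = 0.304 with an estimated correlation). Respiratory chain and TCA cycle genes rose in 19 of 43 tested members (21 adjusted over the list alone, 27 with the array number as a block), such as ATP7 (1.36), QCR6 (0.96), ATP17 (1.27) and COR1 (0.90) (camera adjusted p = 2.75e-06, adjusted p = 0.390 with an estimated correlation). In this list LSC2 fell (-0.95). Ribosome biogenesis genes rose in 10 of 38 tested members (19 adjusted over the list alone, 23 with the array number as a block), led by RPA135 (0.88), DBP9 (0.73), UTP4 (0.76) and RRP12 (0.65) (camera adjusted p = 1.8e-05, adjusted p = 0.310 with an estimated correlation). Core histone genes rose in 3 of 10 tested members (7 adjusted over the list alone, 7 with the array number as a block), HHF1 (0.78), HTB1 (0.59) and HHT2 (0.45), while HHT1 (0.55) did not pass (camera adjusted p = 0.0225, adjusted p = 0.686 with an estimated correlation). With median centring HHF1 (adjusted p = 0.171), HTB1 (0.171) and HHT2 (0.486) did not pass either. SAGA subunit genes, a list that holds TRA1 itself, rose in 3 of 19 tested members (3 adjusted over the list alone, 8 with the array number as a block), TAF12 (0.77), TRA1 and CHD1 (0.50), while SPT3 (0.37) did not pass (camera adjusted p = 0.0433, adjusted p = 0.461 with an estimated correlation). ARG8, CUR1 and LSC2 were named after their values were seen. The lists of general stress, glucose-repressed and ribosomal protein genes were not called in tra1_SRR3413, with medians of -0.08, -0.06 and -0.01. For ribosomal protein genes the mean, 0.04, had the opposite sign. The ribosomal protein list was called by camera in opposite directions without array 1 of tra1_SRR3413 (median -0.29, adjusted p = 0.0306) and without its array 2 (median 0.30, adjusted p = 1.57e-06). It was also called with array 1 of tra1-S3463A counted as tra1_SRR3413 (median 0.13, adjusted p = 0.00376).

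The array number as a block gave 3010 genes for tra1_SRR3413 and the slide as a block 3126, while limma called 717 and 727 genes without array 1 or 2 of tra1-P3408A and 714 and 330 without array 1 or 2 of tra1_SRR3413, where 11 and 23 of the 66 genes named for it lost their call. Without array 1 of tra1_SRR3413 the Hsf1 (adjusted p = 0.161), histone (0.178) and SAGA (0.0509) lists were lost, as were the SAGA list without its array 2 (0.103) or either array of tra1-P3408A (0.0524 and 0.0539) and the histone list with median centring (0.187).

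The comparison of tra1-S3463A with TRA1 asks which genes depend on the serine changed in this allele. There were 532 genes lower and 390 higher. IMD2 fell by 17.1-fold (-4.10 ± 0.42, adjusted p = 0.00152), ADE17 by 10.3-fold (-3.37 ± 0.12, adjusted p = 0.00152) and SPL2 by 7.39-fold (-2.89 ± 0.16, adjusted p = 0.00152). The largest rise was that of SCW10 at 3.03-fold (1.60 ± 0.18, adjusted p = 0.00365), followed by the weak acid exporter PDR12 at 2.90-fold (1.54 ± 0.07, adjusted p = 0.00248).

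Of the 922 genes called in tra1-S3463A, 237 differed by 2-fold or more, and 193 of these were lower. The remaining largest falls were those of YAR075W (-4.41 ± 0.61), HAB1 (-2.76 ± 0.48), AAD4 (-2.65 ± 0.55), HIS4 (-2.46 ± 0.61), ADE1 (-2.45 ± 0.07), BDH2 (-2.34 ± 0.45), YMR090W (-2.34 ± 0.34), TSA2 (-2.32 ± 0.17) and EMI2 (-2.31 ± 0.13), with adjusted p from 0.00152 to 0.00609. TSA2 encodes a thioredoxin peroxidase. After PDR12, the remaining largest rises were those of RNR1 (1.499 ± 0.19), FET3 (1.498 ± 0.30), ATF2 (1.48 ± 0.25), PCL1 (1.45 ± 0.25), SVS1 (1.41 ± 0.03), MNN1 (1.37 ± 0.18), DBP2 (1.34 ± 0.09), HXT4 (1.298 ± 0.16) and RRN3 (1.28 ± 0.26), with adjusted p from 0.00350 to 0.0293, and TRA1 completed the 12. ATF2 encodes an alcohol acetyltransferase and RRN3 an initiation factor of RNA polymerase I. PHO5 fell to -1.95 ± 0.61 (adjusted p = 0.00722) and ADH2 to -1.66 ± 0.13 (adjusted p = 0.00237).

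Among the lists lower in tra1-S3463A, the phosphate (Pho4) regulon had 7 of 15 tested members (10 adjusted over the list alone, 12 with the array number as a block) lower, led by SPL2, PHO84 (-2.04), PHO89 (-0.94) and PHM6 (-0.92) (camera adjusted p = 2.8e-06, adjusted p = 0.246 with an estimated correlation). Gcn4 targets fell in 15 of 36 tested members (18 adjusted over the list alone, 19 with the array number as a block), such as SNZ1 (-2.27), LYS1 (-1.91), SNO1 (-2.02) and LYS20 (-1.96) (camera adjusted p = 2.8e-06, adjusted p = 0.246 with an estimated correlation). Yap1 genes fell in 10 of 22 tested members (13 adjusted over the list alone, 15 with the array number as a block), with GTT2 (-1.85), SOD2 (-0.84), OYE3 (-1.47) and FLR1 (-1.13) leading (camera adjusted p = 2.8e-06, adjusted p = 0.461 with an estimated correlation). Of the Hsf1 chaperone genes, 8 of 25 tested members (10 adjusted over the list alone, 16 with the array number as a block) fell, among them HSP82 (-1.52), CPR6 (-1.22), SSE1 (-0.88) and HSP78 (-0.93) (camera adjusted p = 1.11e-05, adjusted p = 0.461 with an estimated correlation). Proteasome genes fell in 5 of 32 tested members (7 adjusted over the list alone, 17 with the array number as a block), namely PRE10 (-1.06), PRE8 (-0.48), PRE1 (-0.73), RPT3 (-0.56) and RPT5 (-0.44) (camera adjusted p = 3.57e-05, adjusted p = 0.246 with an estimated correlation). General stress genes fell in 7 of 26 tested members (10 adjusted over the list alone, 12 with the array number as a block), with SOL4 (-1.74), PGM2 (-0.77), PNC1 (-0.76) and ALD3 (-1.79) leading (camera adjusted p = 0.0149, adjusted p = 0.762 with an estimated correlation).

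Higher in tra1-S3463A were ribosome biogenesis genes in 14 of 38 tested members (20 adjusted over the list alone, 28 with the array number as a block), led by RPA135 (1.10), DBP9 (0.79), NSR1 (0.83) and UTP4 (0.80) (camera adjusted p = 1.35e-08, adjusted p = 0.246 with an estimated correlation). G1 cyclin and S phase genes rose in 7 of 19 tested members (8 adjusted over the list alone, 13 with the array number as a block), with RNR1, PCL1, CLN1 (1.06) and TOS4 (0.78) leading (camera adjusted p = 3.57e-05, adjusted p = 0.246 with an estimated correlation). Respiratory chain and TCA cycle genes rose in 10 of 43 tested members (15 adjusted over the list alone, 19 with the array number as a block), such as ATP7 (0.99), QCR6 (0.67), ATP17 (1.03) and COX4 (0.94) (camera adjusted p = 0.000526, adjusted p = 0.503 with an estimated correlation). In this list LSC2 fell (-0.76). Of the core histone genes HHF1 (0.69) alone passed, while HHT2 (0.46), HHT1 (0.58) and HTA2 (0.69) did not. That made 1 of 10 tested members (7 adjusted over the list alone, 8 with the array number as a block) higher (camera adjusted p = 0.00246, adjusted p = 0.503 with an estimated correlation), and with median centring HHF1 did not pass (adjusted p = 0.231). Ribosomal protein genes rose in 19 of 133 tested members (19 adjusted over the list alone, 61 with the array number as a block), led by RPL18B (1.06), RPS14B (0.94), RPL26A (0.79) and RPS27A (0.76) (camera adjusted p = 7.7e-06, adjusted p = 0.762 with an estimated correlation). RPT5 and LSC2 were named after their values were seen.

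The array number as a block gave 2635 genes for tra1-S3463A and the slide as a block 2983, while limma called 426 and 436 genes without array 1 or 2 of tra1-P3408A, and 151 and 138 without array 1 or 2 of tra1-S3463A, where 34 and 35 of the 72 genes named for it lost their call. Without array 1 of tra1-S3463A, whose source label names the tra1_SRR3413 strain, the lists of ribosomal protein (median -0.01, adjusted p = 0.211), general stress (median -0.03, adjusted p = 0.614, and 0.631 where that array counted with tra1_SRR3413) and histone genes (adjusted p = 0.0508) were not called.

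**Figure D2:**
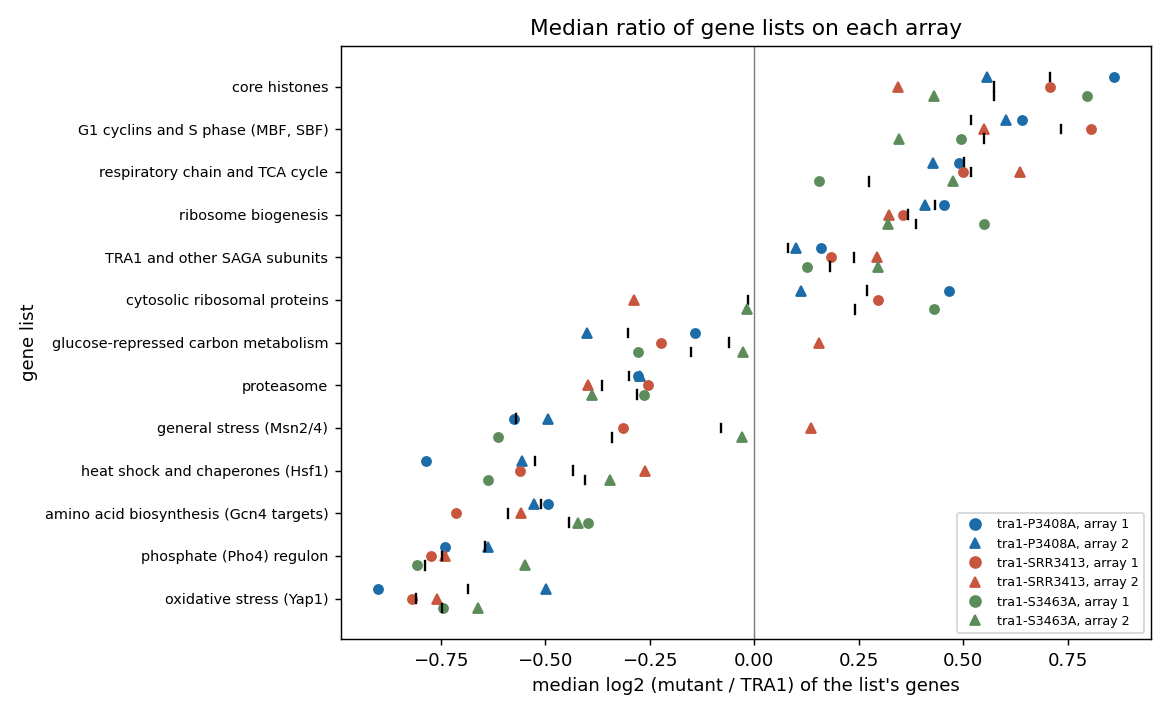
Points are the median log2 (mutant / reference) over the tested members of each gene list called in at least 1 allele, for each array. The Yap1 list has medians of -0.68, -0.81 and -0.75 in tra1-P3408A, tra1_SRR3413 and tra1-S3463A, and the G1 and S phase list medians of 0.52, 0.73 and 0.55.

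Of 32 lists, camera called 12 in tra1-P3408A, 10 in tra1_SRR3413 and 11 in tra1-S3463A, and with an estimated correlation it called 0 in each allele. The lowest adjusted p with an estimated correlation was 0.180 in tra1-P3408A, 0.251 in tra1_SRR3413 and 0.246 in tra1-S3463A. Fry, which tests each list by itself, also called 8, 8 and 7 of the lists that camera called. It did not call general stress (adjusted p = 0.204 and 0.291) or ribosomal protein genes (0.361 and 0.457) in tra1-P3408A and tra1-S3463A. Histone genes were not called by fry in any allele (0.0890, 0.111 and 0.0979). The same held for glucose-repressed genes in tra1-P3408A (0.154), Hsf1 genes in tra1_SRR3413 (0.0694) and respiratory chain genes in tra1-S3463A (0.0926). The other 19 lists, among them NuA4 subunits, ergosterol, iron, mating, galactose, glycolysis and hexose transporter genes, were not called by camera in any allele without a block. Their lowest adjusted p in camera was 0.128 in tra1-P3408A, 0.143 in tra1_SRR3413 and 0.130 in tra1-S3463A. With the array number as a block camera called glycolysis genes lower in tra1-S3463A (adjusted p = 0.0236), as it did with the slide as a block (0.00249). Fry called galactose genes lower in tra1-P3408A (0.00912), tra1_SRR3413 (0.0375) and tra1-S3463A (0.00887), and SAGA genes higher in tra1-S3463A (0.0365).

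The alleles were next compared with each other, to ask whether changes at different places of the PI3K domain altered the same genes. In all 3 alleles 232 genes were higher and 410 lower, among them SCW10, PCL1, RNR1, PDR12, MNN1 and SVS1 on the higher side and IMD2, ADE17, ADE1, SPL2, HIS4, HAB1 and BDH2 on the lower side. Of 1444 genes called in any allele, 0 were called in opposite directions in different alleles, and 1404 had the same sign on all 6 arrays. Between tra1-P3408A and tra1-S3463A, 257 higher and 437 lower genes were shared, where independent lists would share 18.5 and 42.2. Those shared between tra1_SRR3413 and tra1-P3408A numbered 253 and 443, against 27.2 and 56.9 for independent lists. For tra1_SRR3413 and tra1-S3463A they numbered 315 and 480, against 36.4 and 62.4. Part of these excesses, and of the agreement in sign, may come from the reference strain on every array. No value for unchanged alleles was made for the agreement in sign.

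Fold changes of the alleles ran together across genes, which are not independent replicates. Pearson's r was 0.892 between tra1_SRR3413 and tra1-P3408A, 0.932 between tra1_SRR3413 and tra1-S3463A and 0.937 between tra1-P3408A and tra1-S3463A. Spearman's rho was 0.837, 0.908 and 0.897. In 100 simulated sets of unchanged alleles, r was 0.667 where 1 reference extract served all arrays and 0.499 where each array number had its own. The covariances were 0.207, 0.223 and 0.193, against 0.0307 or 0.0153 in those simulations. The simulations assumed that reference and mutant extracts vary equally, which fixes their values of r. A deviation of 1 extract used on every array does not enter the spread between arrays, so its size is unknown. How far the covariances exceed what a shared reference gives therefore stays open. Single arrays of the same number in different alleles correlated at 0.754 to 0.955, and the 2 arrays of an allele at 0.639 to 0.765. Leaving out array 1 of tra1_SRR3413 lowered r with tra1-P3408A to 0.724, and leaving out array 1 of tra1-S3463A lowered r with tra1-P3408A to 0.758.

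**Figure D3:**
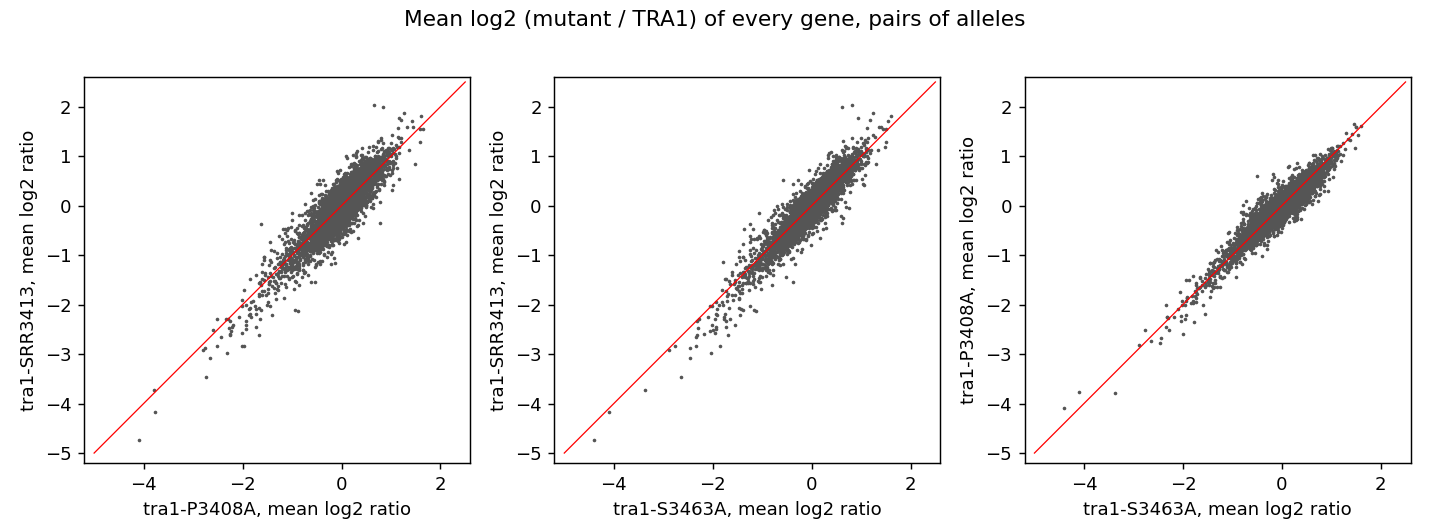
Each point is a gene, placed by its mean log2 (mutant / reference) in the alleles on the axes, with the line of equal values in red. The genes lie along the line, with r of 0.892, 0.932 and 0.937.

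No gene passed in a test of the difference between alleles. The fit without a block ignored the correlated deviations of arrays of the same number. Deviations that alleles share cancel in a difference but stay in the spread of that fit. Its p-values for differences thus tend to be too large and its intervals too wide. Counts below those given by chance therefore do not show that the alleles are alike. For tra1_SRR3413 minus tra1-P3408A, limma called 0 genes, with 105 at an unadjusted p under 0.05 where chance gives 306. With the array number or the slide as a block it called 0, with 742 and 467 at an unadjusted p under 0.05. The genes with the strongest statistics were GCY1, an aldo-keto reductase gene, at 0.84 (95% confidence interval 0.45 to 1.22), and FLR1, a drug exporter gene, at -1.23 (95% confidence interval -1.86 to -0.60). OM45 (0.72), YBR085C-A (0.55), HSP42 (0.77) and UIP4 (0.97) stood on the higher side, and DSE3 (-0.75), OSI1 (-1.18), YLL053C (-0.65) and AQY1 (-0.93) on the lower. All 10 had an adjusted p of 0.998. On slide 1, which held array 1 of both alleles, the differences of GCY1 and FLR1 were 0.88 and -0.80.

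For tra1_SRR3413 minus tra1-S3463A limma also called 0 genes, with 105 at an unadjusted p under 0.05 against 306 by chance. With the array number or the slide as a block the call was 0 again, with 502 and 908 unadjusted. GCY1 stood at 0.91 (95% confidence interval 0.52 to 1.29) and AQR1, an exporter gene, at -0.79 (95% confidence interval -1.14 to -0.43). The others were YBR085C-A (0.70), CUR1 (0.66), RTC3 (0.63), PGM2 (0.58), AQY1 (-1.16), GCV2 (-0.87), DSE3 (-0.73) and SCW11 (-0.82), each with an adjusted p of 0.9996. On slide 3, which held array 2 of both alleles, the differences of GCY1 and AQR1 were 0.82 and -0.70.

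For tra1-P3408A minus tra1-S3463A limma called 0 genes, with 6 at an unadjusted p under 0.05 against 306 by chance. With the array number or the slide as a block it called 0, with 88 and 418 unadjusted. The glycine cleavage gene GCV2 stood at -0.64 (95% confidence interval -1.06 to -0.22) and SHM2 at -0.57 (95% confidence interval -0.96 to -0.18). The others were YOR024W (0.53), YIL100W (0.52), YIL141W (0.39), TIS11 (0.37), FDH2 (0.57), MIX23 (-0.58), URA2 (-0.48) and ADE17 (-0.42), each with an adjusted p of 0.999. On slide 2, which held array 2 of tra1-P3408A and array 1 of tra1-S3463A, GCV2 and SHM2 differed by -0.54 and -0.60. A difference between alleles had a median 95% confidence half-width of 0.49 over genes. Of simulated log2 differences 0% to 5.97% were recovered at a size of 0.5 and 35.8% to 61.2% at a size of 1, so 2-fold differences were often missed in the simulation. It lacked the correlated deviations of arrays of the same number, so these shares do not give the power on the real arrays.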

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

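In this part the tests of gene lists between alleles and all tests of explanations were chosen after the results were seen, except the test of whether array 1 of tra1-S3463A held another strain's RNA.

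Gene list shifts differed between alleles by camera at its preset correlation, although no single gene passed. General stress genes were higher in tra1_SRR3413 than in tra1-P3408A by a median of 0.47 (camera adjusted p = 1.1e-09) and than in tra1-S3463A by 0.35 (2.09e-09). Ribosomal protein genes were lower in tra1_SRR3413, with a median difference of -0.27 from tra1-P3408A (9.38e-13) and -0.25 from tra1-S3463A (8.08e-13). Of 32 lists, 9 differed between tra1_SRR3413 and tra1-P3408A, 14 between tra1_SRR3413 and tra1-S3463A, and 2 between tra1-P3408A and tra1-S3463A. With an estimated correlation 0 differed in any pair, and the lowest adjusted p values were 0.567, 0.378 and 0.980. The correlation estimated between genes was 0.508 for general stress and 0.558 for ribosomal protein genes, far above the preset of 0.01. The camera p-values printed for these lists at the preset are therefore too small. On arrays 1 and 2 the median differences of general stress genes between tra1_SRR3413 and tra1-P3408A were 0.32 and 0.59, and those of ribosomal protein genes -0.19 and -0.39. Between tra1_SRR3413 and tra1-S3463A they were 0.39 and 0.33, and -0.17 and -0.34. Arrays 1 of tra1_SRR3413 and tra1-P3408A shared slide 1, and arrays 2 of tra1_SRR3413 and tra1-S3463A slide 3.

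The remaining lists called between tra1_SRR3413 and tra1-P3408A had median differences (and those on arrays 1 and 2) of -0.11 (-0.14 and -0.10) for Gcn4 targets, 0.27 (0.12 and 0.43) for Hsf1 chaperones, -0.0924 (-0.07 and -0.14) for ribosome biogenesis, 0.19 (0.00 and 0.40) for glucose-repressed genes, -0.0627 (-0.16 and -0.06) for nitrogen catabolite repression, -0.21 (-0.21 and -0.28) for a-cell genes and -0.22 (-0.07 and -0.36) for Yap1 genes. The nitrogen and ribosome biogenesis lists were not called between these alleles with the array number as a block (adjusted p = 0.0594 and 0.0534), while cell wall integrity genes gained a call between tra1_SRR3413 and tra1-S3463A (0.0618 without the block and 0.0404 with it). The median differences between tra1_SRR3413 and tra1-S3463A were -0.17 (-0.14 and -0.19) for Gcn4 targets, -0.14 (-0.07 and -0.17) for ergosterol synthesis, 0.13 (0.07 and 0.19) for Hsf1 chaperones, -0.11 (-0.16 and -0.06) for ribosome biogenesis and 0.17 (0.25 and 0.09) for the respiratory chain and TCA cycle. The same pair differed by 0.13 (0.14 and 0.07) for glucose-repressed genes, 0.22 (0.24 and 0.16) for methionine and sulfate genes, -0.11 (-0.14 and -0.11) for nitrogen catabolite repression, -0.20 (-0.41 and -0.04) for a-cell genes, -0.21 (-0.08 and -0.27) for Yap1 genes, 0.12 (0.10 and 0.16) for the DNA damage response and 0.10 (0.13 and 0.10) for G1 and S phase genes. Between tra1-P3408A and tra1-S3463A they were 0.0857 (0.23 and -0.11) for the respiratory chain and TCA cycle and 0.16 (0.07 and 0.25) for methionine and sulfate genes. Between these alleles the direction for the respiratory chain and TCA cycle turned between arrays 1 and 2. Glucose-repressed genes differed between tra1_SRR3413 and tra1-P3408A by 0.000102 on arrays 1, so arrays 2 alone carried that difference. Slide 2 held tra1-P3408A and tra1-S3463A in opposite dyes, so its differences mix in dye orientation.

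Some named genes stood on opposite sides of 0 on all arrays of 2 alleles, differences that were not tested as such and whose genes did not pass in the tests between alleles. UIP4 differed by 0.97 between tra1_SRR3413 and tra1-P3408A. YLL053C stood lower in tra1_SRR3413, with differences of -0.65 and -0.62 against tra1-P3408A and tra1-S3463A. CUR1, of the Hsf1 list, stood higher there by 0.60 and 0.66. SCW11 stood lower there, with differences of -0.69 and -0.82. MIX23 stood higher in tra1-S3463A than in the other alleles, with differences of -0.72 for tra1_SRR3413 and -0.58 for tra1-P3408A. URA2, a pyrimidine synthesis gene, differed by -0.48 between tra1-P3408A and tra1-S3463A.

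The same genes fell and rose in all 3 alleles. Dye bias was argued against, since arrays 1 and 2 of an allele, with the dyes swapped, correlated at 0.639 or more after turning, where dye bias would have made r negative. A lower growth rate of the mutants was argued against as the whole cause, because it would lower ribosome biogenesis genes, whose lowest median was 0.37. That covers growth rate alone, and a difference in culture stage at harvest was not tested and stays open. A peculiarity of the reference strain's cultures cannot be told apart from an effect that the alleles share, because that strain was on every array, and with the array number as a block at most 742 genes differed between alleles at an unadjusted p under 0.05, against 306 by chance. That explanation and a shared effect of PI3K domain changes, the biological one, both stay open.

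Arrays of the same number resembled each other more, on average, than arrays of the same allele. The array number, and with it the dye orientation, cannot be told apart from other causes, because the correlation of deviations from the allele means, 0.467 or more in every pair of alleles, restates the pattern, and array 2 of tra1-P3408A was closer to arrays 1 of the other alleles (0.802 and 0.816) than to their arrays 2 (0.754 and 0.779). A shared slide was argued against for arrays 1, of which those on different slides correlated at 0.941 or more, against 0.765 at most for arrays of the same allele, but not for arrays 2, which correlated at 0.924 on the same slide and lower on different slides. Whether array 1 of tra1-S3463A held RNA of the tra1_SRR3413 strain, as its source label says, was tested on the difference between these alleles. That difference repeated between arrays 1 and arrays 2 with an r of 0.702, where such a mix-up was predicted to leave r near 0. The same r was 0.208 for tra1_SRR3413 minus tra1-P3408A and -0.296 for tra1-P3408A minus tra1-S3463A. How far r would stray from 0 under a mix-up was not measured. Day of culture may share the array number and was not given in the sources used here, so dye and day stay open, as does the slide for arrays 2.

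TRA1 mRNA was higher in the mutants. The arrays of slide 3, which had the highest Cy3 signals, were argued against as its cause, because TRA1 was 0.73 or more on the 4 other arrays, though the larger values of tra1_SRR3413 and tra1-S3463A rested on slide 3. More copies of the plasmid cannot be told apart from other causes with these data. Its marker LEU2 reached -0.17 at most, but LEU1, a gene under the same regulator, Leu3, fell to -2.01 ± 0.28, -1.90 ± 0.24 and -1.59 ± 0.04, so a copy gain may have been masked in LEU2. A change of TRA1 expression in response to the alleles, the biological explanation, stays open and untested.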

How the results depend on the processing

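The alternative without the arrays of slide 3 was chosen after seeing the data, and the others before the data were examined. The counts of genes called in an allele, both directions together, stayed within 1.5 times under Agilent's processed signals, median centring, the deposited log ratios, the series matrix, and looser and stricter filters on dim probes. The genes themselves changed more. With median centring 502 of the 776 calls in tra1-P3408A, 980 of 1289 in tra1_SRR3413 and 656 of 922 in tra1-S3463A were kept. Higher genes in tra1-P3408A then numbered 161 in place of 291, and lower ones 368 in place of 485. Differences between alleles stayed at 0 genes by limma in every alternative that covered them, with the unadjusted counts given in the report. With the array number as a replicate block the counts were 2214 for tra1-P3408A, 3010 for tra1_SRR3413 and 2635 for tra1-S3463A. All calls of the fit without that block were kept, and of the lists called 12, 10 and 11 were kept, while glycolysis genes in tra1-S3463A gained a call (adjusted p = 0.0236), as with the slide as a block (0.00249). The block made TRA1 pass in tra1-P3408A and ended no call of a named gene. This block leaves each allele's mean as it was and takes shared deviations out of the spread. That calls were kept was thus nearly fixed in advance and says little about how firm they are. With the slide as a block the counts were 2679, 3126 and 2983, and the median of ribosomal protein genes in tra1_SRR3413, -0.0137 without a block, turned to 0.0117. Counting array 1 of tra1-S3463A with tra1_SRR3413 gave 2004 genes for tra1_SRR3413 and 326 for tra1-S3463A, and r of 0.758 between tra1-P3408A and tra1-S3463A. The median of ribosomal protein genes then turned to 0.130 in tra1_SRR3413 and -0.0166 in tra1-S3463A. Only the 2 arrays of tra1-P3408A in the fit, like leaving out slide 3, gave 1571 genes for it. Leaving out slide 3 also turned URA3 in tra1-S3463A to 0.0467. Asking in addition for 1.5-fold on both arrays left 484, 659 and 513 genes, by construction. Leaving out each array in turn gave 1 to 801 genes for tra1-P3408A, 330 to 1218 for tra1_SRR3413 and 138 to 963 for tra1-S3463A, where a lone array was assumed to vary like the other alleles. Correlations then ran from 0.724 to 0.932 for tra1_SRR3413 and tra1-P3408A, 0.825 to 0.932 for tra1_SRR3413 and tra1-S3463A, and 0.758 to 0.947 for tra1-P3408A and tra1-S3463A. Without array 1 of tra1_SRR3413 its medians were 0.136 for general stress, 0.154 for glucose-repressed and -0.287 for ribosomal protein genes, and without its array 2 -0.314, -0.222 and 0.296. Ribosomal protein genes in tra1-S3463A had medians of -0.0133 and 0.430 without its array 1 or 2. URA3 was at -0.124 and 0.0901 in tra1-P3408A without its array 1 or 2, and at -0.303 and 0.0467 in tra1-S3463A. Glucose-repressed and SAGA genes, not called in tra1-S3463A, were called there by camera with median centring (adjusted p = 0.0364 and 0.0110), and also with the deposited log ratios (0.0450 and 0.0469) and the series table (0.0445 and 0.0473). Glucose-repressed genes were called too with Agilent's processed signals (0.0454), the slide as a block (0.0347) and without its array 2 (0.00357), but not without its array 1 (median -0.0279, 0.614). Of 2556 values of named genes under alternatives other than leaving out single arrays, 95 lost their call, 24 gained 1 and 1 turned sign, with the histone genes lost under median centring. Median centring lost 25 calls, as did counting array 1 of tra1-S3463A with tra1_SRR3413. Quantile scaling, both filters on dim probes and both blocks lost 0. The share over all values is therefore no measure of how firm the calls are. Medians of lists not called in any allele, of which many turned sign in a first run, were not followed. Except where fewer arrays or a stricter criterion explain it, the cause was not tested. Quantile scaling of average intensities left every ratio as it was, and choosing the brightest probe had no effect since each gene had 1 probe. Distances of 15, 30 and 50 kb from chromosome ends were not run, since the files name no genome build. Signal over background limited little, and 2 genes were too dim to test.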

Other observations

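The lists of purine and one-carbon genes and of outermost genes in this part, and their tests, were chosen after the results were seen.

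Genes of purine synthesis and one-carbon metabolism, most of them regulated by Bas1 and Pho2, fell together. Of 16 tested members, 14 fell in tra1-P3408A, 15 in tra1_SRR3413 and 14 in tra1-S3463A, and 0 rose in any allele by limma. Beside ADE17 and ADE1, ADE5,7 fell to -2.25 ± 0.10, -2.59 ± 0.13 and -2.18 ± 0.18, and ADE13 to -1.62 ± 0.02, -1.60 ± 0.13 and -1.40 ± 0.04. The glycine cleavage genes GCV1 (-1.85 ± 0.12, -2.07 ± 0.14 and -1.46 ± 0.32) and GCV2 (-2.19 ± 0.03, -2.42 ± 0.22 and -1.55 ± 0.12) and the one-carbon gene MTD1 (-1.82 ± 0.13, -1.95 ± 0.56 and -1.81 ± 0.79) fell as well. ADE3 did not pass in any allele (-0.70 ± 0.27, -0.48 ± 0.50 and -0.55 ± 0.47). The list's medians were -1.72, -1.98 and -1.50, and camera with an estimated correlation gave an unadjusted p of 0.00588, 0.00719 and 0.00726. The IMD genes of GTP synthesis fell too, IMD3 to -1.83 ± 0.16, -2.25 ± 0.26 and -1.77 ± 0.37 and IMD4 to -0.78 ± 0.05, -1.31 ± 0.18 and -0.78 ± 0.24, with the limit that IMD1, IMD2, IMD3 and YAR075W share sequence.

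A hypothesis is that the falls of ADE17, ADE1 and SHM2 belong to a common fall of the genes under Bas1 and Pho2. Over the 12 members outside the largest falls the median was -1.37 or lower in every allele, which such a common fall needs, and single falls of a few genes would have left it near 0. Since the list was chosen after the results were seen, that median describes its members and is no independent test. HIS1, HIS4 and ADE4 are also on the Gcn4 list, so these data may show 1 loss or several.

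Genes near chromosome ends were followed by gene order, as the outermost 10 protein-coding genes of each chromosome arm in the R64 table, of which 292 were tested. Of these 36 fell and 7 rose in tra1-P3408A, 52 fell and 15 rose in tra1_SRR3413, and 36 fell and 15 rose in tra1-S3463A. Falls also outnumbered rises over all 6119 tested genes, with 485 against 291, 718 against 571 and 532 against 390. The medians of the outermost genes were -0.09, -0.08 and -0.09. Camera gave an unadjusted p of 0.00790, 0.0333 and 0.0360, and with an estimated correlation 0.151, 0.222 and 0.227.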
